A study of Mus musculus with 16 samples.

How the data were processed

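RNA from adherent mouse peritoneal cells was measured on 16 single-colour arrays, 4 from each of 4 groups: control cells and cells labelled fld, each left untreated or given LPS at 100 ng/ml over 5 h. Per the labels, cells were washed out of the peritoneum of male mice, left to adhere, rinsed free of cells that had not attached, and treated in medium without serum. The control mice were heterozygotes of the fld strain on a BALB/cByJ background, and the mutant mice carried fatty liver dystrophy (fld), a mutation of Lpin1, the gene of the phosphatidate phosphatase lipin-1. Per the labels, RNA was extracted with Trizol, amplified, labelled with Cy3 and hybridised. The design text names 4 control and 4 fld mice. Whether a replicate number marks the same mouse in the untreated and LPS groups is not stated, and if arrays of a group do not come from separate mice the p-values measure technical spread only.

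Each deposited scanner file held the intensity of 45018 spots, 43379 of them not controls, read by Agilent Feature Extraction 9.5.1.1 on array design 014868, per the file headers. Per the file headers, the authors' processed intensity had been background-subtracted, corrected for trends across the slide, and replaced by a small surrogate value for spots too dim to subtract. The series' value table, also deposited, holds other values, a linear unit that its labels leave unstated. Set against the scanner values, each of its columns was the processed intensity divided by that array's median, with every column median at 1. Its scale and direction are therefore known, and it carries no centring by gene.

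The processed intensity was taken to log2 and each array's 75th percentile was subtracted. Control spots were left out, and spots with an outlier flag were set to missing, 1.26% of values. Spots of one probe were averaged, and 245 probes had repeated spots. A probe was kept when it was well above background on all 4 arrays of at least 1 group, which left 25535 of 41174 probes. Names came from the accession of a probe through a RefSeq gene table of assembly GRCm38.p6 for 22951 probes, from the symbol in the files for 6659 and from a synonym for 3109, and 8455 probes kept the name in the files. That table gave names only. Probe coordinates are those in the scanner files, whose genome build is not given in the sources used here. Where several probes of a gene remained, the brightest over all arrays stood for it (5677 features), which left 17462 features, 13521 of them with a gene symbol. For Lpin1 all 4 probes are described separately.

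Groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 16 arrays (lmFit, then eBayes) and Benjamini-Hochberg adjustment within each comparison at an adjusted p under 0.05. All p-values of limma are two-sided. There were 5 comparisons: LPS against untreated in control cells, the same in cells labelled fld, fld against control without LPS, fld against control with LPS, and the difference between the LPS responses of the genotypes. Fold changes are LPS over untreated or fld over control, on the log2 scale, and SE is the standard error from limma. Where a probe was not well above background on any array of a group, its change is given as a bound: the mean of the brighter group against, per array of the dimmer group, the higher of the lowest signal among probes well above background and the probe's own signal.

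In total 29 gene lists with 631 genes, 623 of them on the array and 6 of the 631 in 2 lists, were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison. Alternatives were camera with an estimated correlation, fry, and an exact two-sided permutation test on the list's mean per array, which has 70 labellings and a smallest p of 0.0286. With an estimated correlation, only the NF-kB list in control cells under LPS was called. No list passed the exact test after adjustment, in any of the 4 comparisons it covers. With 29 lists adjusted together, a list could pass only if most lists reached the smallest p. These failures after adjustment therefore do not count against a list. Medians of the lists called between genotypes were also set beside those of 10000 random lists of matched signal, chosen after the data were seen. The lists, the groups, the design of each test, the other settings to be tried and the rule for naming genes were fixed before the data were examined. By that rule the text names the lipins and 11 inflammatory and lipid genes, the 6 highest and 6 lowest changes among called features whose groups do not overlap, and, from each list that was called or held at least 3 called members, up to 3 members in its main direction and up to 2 in the other. Further list members are named where few were called, and other genes are said to be chosen afterwards. The single-gene results of 3 list members are not reported here; they stay in the counts and tests of their lists.

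Settings fixed in advance changed the background correction (normexp with an offset of 50), the scaling (median, quantile, the authors' value table), the filter, the probe rule, a floor, the empirical Bayes options, array weights, the arrays in the fit, the replicate number as a fixed or random block, the threshold and each array in turn. Added after seeing the data were normexp with extreme local backgrounds reset, cyclic loess between arrays, and a fit without the arrays labelled fld replicate 4. The code was tested on simulated data, with 67, 67 and 66 of 17462 features changed 1.5-, 2- and 4-fold. Each feature was drawn independently, with its own spread pooled over the 4 groups. Unequal spread between groups and features that move together were thus not simulated. For LPS against untreated in control cells it recovered 34.3%, 59.7% and 98.5% of them, and in cells labelled fld 31.3%, 74.6% and 97.0%. For fld against control it recovered 32.8%, 68.7% and 90.9% without LPS and 43.3%, 65.7% and 92.4% with LPS. For the difference between responses it recovered 5.97%, 49.3% and 83.3%. In the same order of comparisons, 5, 11, 5, 14 and 5 unchanged features were called. Data handling used Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots used matplotlib 3.10.9.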

Results

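Gene expression in adherent peritoneal macrophages was compared between control heterozygotes and mice labelled fld, without treatment and after 5 h of 100 ng/ml LPS, a bacterial ligand of TLR4, to ask what lipin-1 does to gene expression during TLR4 stimulation. Each of the 4 groups held 4 arrays. Between 58.7% and 65.4% of the spots of an array were well above background, and the 75th percentile of the processed intensity lay between 189 and 627. Replicates of a group correlated at 0.962 to 0.993 across features, and the median SD between replicates was 0.20, 0.19, 0.19 and 0.26 log2 units in untreated control, LPS control, untreated fld and LPS fld arrays. The number of arrays limits the precision. Each group was hybridised on 1 slide of its own and scanned with it, so slide and group cannot be told apart in any comparison.

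Lpin1 (gene 14245), the gene mutated in fld, was measured by 4 probes, all on chromosome 12 in the coordinates of the scanner files. The brightest probe (16590760 to 16590818) did not separate the genotypes. Its log2 level was -1.52 ± 0.22 in untreated control and -1.53 ± 0.13 in LPS control arrays, and -1.64 ± 0.69 and -1.25 ± 0.63 in untreated and LPS arrays labelled fld (SD, n = 4 each). Replicates 1 to 4 read -1.50, -1.81, -1.44 and -1.30 in untreated control, -1.46, -1.40, -1.69 and -1.57 in LPS control, -1.84, -1.96, -2.15 and -0.63 in untreated fld, and -1.59, -1.40, -1.69 and -0.33 in LPS fld. The other 3 probes lie close together (16591574 to 16591633, 16591634 to 16591693 and 16591654 to 16591713). Their mean was -3.11 ± 0.31 in untreated control and -3.23 ± 0.26 in LPS control arrays (SD, n = 4). In arrays labelled fld, replicates 1 to 3 lay between -6.72 and -6.07 untreated and between -6.19 and -5.46 with LPS, below every control array. Replicate 4 lay at -1.62 untreated and -3.03 with LPS, at or above the control level. Over all 4 arrays none of these 3 probes passed limma's test between genotypes, with log2 differences of -1.33, -2.70 and -2.24 untreated (adjusted p = 0.508, 0.171 and 0.171) and -1.58, -2.28 and -1.92 with LPS (adjusted p = 0.305, 0.171 and 0.163). These differences are fitted values: in arrays labelled fld each of the 3 probes was well above background on 1 of 4 untreated arrays, and on 1, 1 and 2 of 4 with LPS. Where the probes lie relative to the fld lesion is not given in the sources used here, and a probe outside the altered part checks nothing about genotype. Because the arrays labelled fld replicate 4 carry Lpin1 signal that the other arrays labelled fld lack, the group is called labelled fld throughout, and each direction between genotypes rests on the labels.

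**Figure D1:**
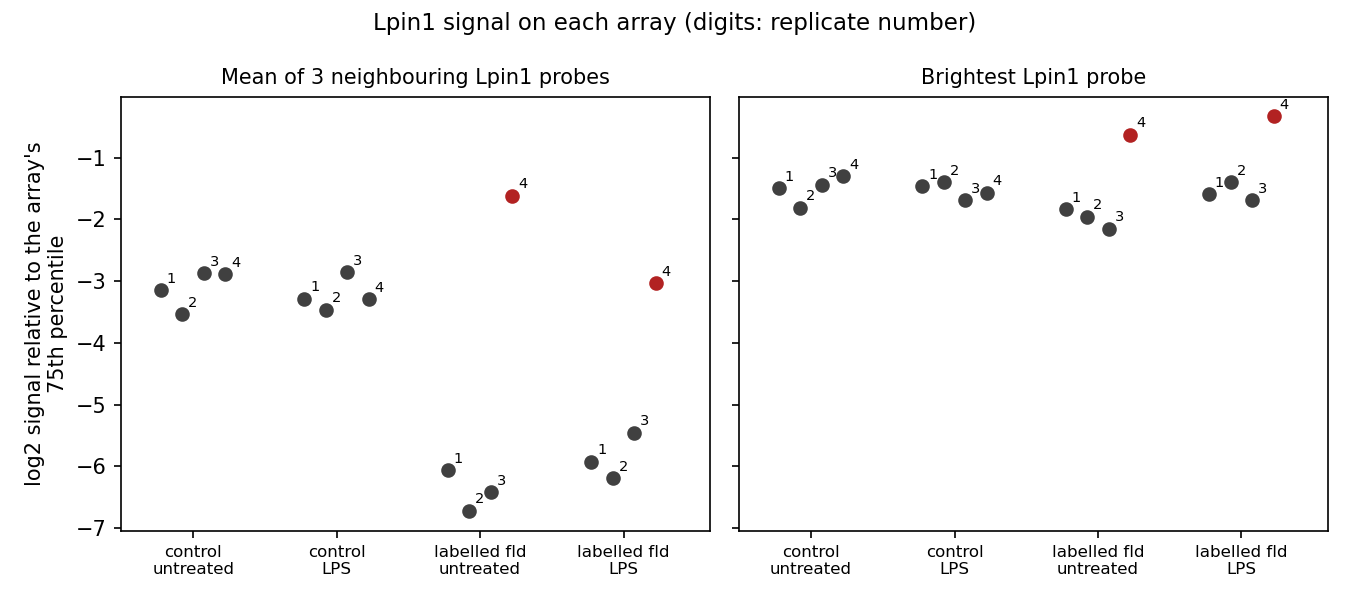
Log2 signal relative to the 75th percentile of each array, for the mean of the 3 neighbouring Lpin1 probes (left) and for the brightest Lpin1 probe (right), with 1 digit per array giving its replicate number in each of the 4 groups. In the left part replicates 1 to 3 labelled fld lie at or below -5.46, while replicate 4 (red) lies at -1.62 untreated and -3.03 with LPS.

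In control macrophages LPS raised 24 of 33 cytokines and chemokines and 20 of 24 NF-kB targets and feedback regulators, while 16 of 32 lysosomal, 11 of 28 fatty acid oxidation and 7 of 17 cholesterol-handling genes fell. Il6 (gene 16193) rose by 5.05 log2 units (SE 0.53, adjusted p = 7.7e-06), and Csf2, which encodes the growth factor GM-CSF, rose by 9.61 (SE 0.60). On control untreated replicate 3 Il6 lay at -0.60, against 2.30 to 2.69 on the rest of its group, which enlarges the Il6 rise. Il1b rose by 2.46 (SE 0.19), Ptgs2, the inducible cyclooxygenase, by 4.01 (SE 0.38), Cxcl1 by 3.09 (SE 0.27) and Il10 by 2.07 (SE 0.37). Nos2, inducible nitric oxide synthase, was not well above background on any untreated control array and rose at least 6.79-fold. In total 5143 of 17462 features passed the test, 2537 higher and 2606 lower with LPS.

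Among all called features whose arrays do not overlap between the groups, the highest changes by fitted value were those of Csf2, Il19 (at least 159-fold), Csf3 (7.93, SE 0.50), Tpbpa (at least 40.3-fold), the hyaluronan synthase Has1 (6.65, SE 0.31) and the kinase Hunk (6.57, SE 0.71). Ranks of genes given as a bound are not measured. Untreated, Csf2 was well above background on 3 of 4 arrays and Hunk on 1. The lowest were those of Rnf144b (-5.49, SE 0.36), Gpnmb (at least 10.8-fold lower) and Hacd4 (-4.01, SE 0.31), and with LPS Rnf144b was well above background on 1 of 4 arrays. Of the genes fixed for naming, Tnf rose by 1.54 (SE 0.20), Ccl2 by 2.97 (SE 0.64), and Il12b, which encodes the p40 subunit of interleukin-12, at least 3.42-fold. Ifnb1 (-0.84, SE 0.67, adjusted p = 0.38), Lpin2 (-0.31, SE 0.16, adjusted p = 0.17), Plin2, which coats lipid droplets (0.07, SE 0.23, adjusted p = 0.86), and the brightest Lpin1 probe (-0.01, SE 0.31, adjusted p = 0.98) did not pass.

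Of the 33 measured cytokines and chemokines in control cells 24 rose, 1 fell and 8 did not pass, and 24 rose and 2 fell when adjusted over the list alone (median 2.36). The camera adjusted p was 2.9e-13, and adjusted p = 0.11 with an estimated correlation. Il1a rose by 4.80 (SE 0.28), Il23a at least 15.1-fold, and Il18 fell by 1.12 on the log2 scale. Of 24 NF-kB targets and feedback regulators 20 rose and 4 did not pass (23 rose adjusted over the list alone; median 1.24). Camera gave adjusted p = 7.2e-16, and adjusted p = 0.032 with an estimated correlation. Among them, inhibitors of the pathway rose, Tnfaip3 by 2.79 (SE 0.14), Tnip1 by 2.45 (SE 0.17) and the RNase gene Zc3h12a by 3.02 (SE 0.16). AP-1, immediate early and MAPK phosphatase genes also went up, with 13 of 24 higher, 1 lower and 10 not past the test (13 and 1 adjusted over the list alone), such as Dusp16 (2.56), Maff (2.48) and Fosl1 (1.87), while Egr2 fell by 0.81. By camera the list had adjusted p = 0.0038, against adjusted p = 0.61 with an estimated correlation. Genes of the unfolded protein and integrated stress responses rose in 13 of 24 cases with 11 not past the test (15 adjusted over the list alone), among them Chac1 (1.86), Herpud1 (1.39) and the chaperone cofactor Dnajb9 (1.13). This list reached adjusted p = 1.8e-06 by camera and adjusted p = 0.079 with an estimated correlation.

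Lower in control cells with LPS were 16 of 32 lysosome and autophagy genes, with 1 higher and 15 not past the test (17 lower and 2 higher adjusted over the list alone; median -0.54). The camera adjusted p was 0.00050, and adjusted p = 0.96 with an estimated correlation. They include Atg7 (-1.26) and the protease gene Ctsb (-0.91). Of 28 fatty acid oxidation genes and PPAR targets 11 fell and 17 did not pass (11 adjusted over the list alone; median -0.29), with Cpt1a, which controls fatty acid entry into mitochondria, at -1.73 (SE 0.15), Acaa2 at -0.76 and Hadh at -0.78. Camera gave adjusted p = 0.0030, and adjusted p = 0.51 with an estimated correlation. Of 17 LXR targets and cholesterol-handling genes 7 fell, 2 rose and 8 did not pass (7 and 2 adjusted over the list alone). By camera the list had adjusted p = 0.041, against adjusted p = 0.96 with an estimated correlation. Nceh1 fell by 2.60, Soat1 by 1.62 and Npc1 by 1.30, while Ch25h, which makes 25-hydroxycholesterol, rose by 4.63 (SE 0.61). Interferon-stimulated genes as a list were lower, with 7 of 34 lower, 1 higher and 26 not past the test (6 lower adjusted over the list alone; median -0.45), among them Iigp1 (-3.01), Ifit2 (-2.79) and Irf1 (-0.84). This list reached adjusted p = 0.0084 by camera and adjusted p = 0.96 with an estimated correlation. This interferon call was lost without control untreated replicate 1 (camera adjusted p = 0.171) or control LPS replicate 3 (0.0553). The LXR call was lost without control LPS replicate 4 (0.0629), control untreated replicate 1 (0.0518), fld untreated replicate 3 (0.0507) or fld untreated replicate 4 (0.0515).

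Other lists had members that changed in control cells without a call for the list. Of 27 TLR4 pathway components 9 rose and 5 fell (10 and 6 adjusted over the list alone), with Map3k8 at 2.00 and Mapk14 at -1.18. Of 21 genes of eicosanoid synthesis and receptors 5 rose and 7 fell (5 and 7 adjusted over the list alone): Ptgs2 and the phospholipase gene Pla2g4a (1.34) rose, and the leukotriene and thromboxane synthase genes Ltc4s and Tbxas1 fell by 2.55 and 2.05. Of 28 glycerolipid synthesis genes 8 rose and 4 fell (8 and 6 adjusted over the list alone), with Dgat2, of triglyceride synthesis, at 1.30 and Cds2 at -1.10. Of 18 genes of lipid droplets, lipid uptake and lipolysis 2 rose and 6 fell (3 and 7 adjusted over the list alone), and its median was 0.12 while its mean was -0.20. The lysosomal lipase gene Lipa fell by 3.11 (SE 0.34), Cd36 by 1.54 and Pnpla2 by 0.89, and Hilpda rose by 2.08. Of 21 glycolysis and hypoxia genes 6 rose and 6 fell (6 and 7 adjusted over the list alone; median -0.16, mean 0.09), with Pfkfb3 at 3.04 and Slc2a1 at 1.27. Of 18 oxidative stress genes 4 rose and 5 fell (4 and 5 adjusted over the list alone; median -0.39, mean 0.02), with Mt2 at 3.17 and Gstm1 at -1.66. Of 17 alternative activation genes 3 rose and 4 fell (4 and 5 adjusted over the list alone), with Il4ra at 2.05 and Igf1 at -1.26. Of 30 sterol and fatty acid synthesis genes 2 rose and 2 fell (2 and 2 adjusted over the list alone; the list was called higher without control untreated replicate 3, camera adjusted p = 0.0413), of 28 cell cycle genes 2 rose and 1 fell (2 and 1 adjusted over the list alone), and of 35 oxidative phosphorylation genes 3 rose and 1 fell (0 adjusted over the list alone).

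Of the 5143 calls, 4605 had no overlap between the 4 untreated and 4 LPS arrays, as had 5790 of all features, where chance gives 2.86%. The count lay between 4163 and 5884 with any 1 array left out. With the planned normexp background, whose fit failed on 2 arrays because of a few spots with extreme local background, it was 1107, and Tnf, Ccl2, Il12b, Gpnmb, Herpud1, Dnajb9, Egr2, Irf1 and Atg7 were among the calls that ended. With those spots reset it was 4042.

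In arrays labelled fld LPS raised 24 of 33 cytokines and chemokines and 19 of 24 NF-kB targets, while 20 of 34 interferon-stimulated, 19 of 32 lysosomal and 9 of 17 cholesterol-handling genes fell. Il6 rose by 3.26 log2 units (SE 0.53, adjusted p = 0.00030), Il1b by 2.07 (SE 0.19), Ptgs2 by 3.57 (SE 0.38), Cxcl1 by 2.77 (SE 0.27) and Il10 by 3.36 (SE 0.37). Tnf rose by 0.84 (SE 0.20), Ccl2 by 2.45 (SE 0.64), Nos2 by 1.68 (SE 0.37) and Il12b at least 3.15-fold. In total 6922 of 17462 features passed the test, 3779 higher and 3143 lower. Ifnb1 (-0.84, SE 0.67, adjusted p = 0.33), Lpin2 (-0.34, SE 0.16, adjusted p = 0.11), Plin2 (0.56, SE 0.23, adjusted p = 0.070) and the brightest Lpin1 probe (0.39, SE 0.31, adjusted p = 0.33) did not pass. Plin2 was called without fld untreated replicate 3 (0.68, adjusted p = 0.045) or fld LPS replicate 2 (0.69, 0.042), Lpin2 without fld LPS replicate 3 (-0.48, 0.022), and the Lpin1 probe without fld untreated replicate 4 (0.73, 0.040) or both arrays labelled fld replicate 4 (0.42, 0.040).

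The highest changes by fitted value in arrays labelled fld were those of Il19 (at least 207-fold), Csf2 (8.13, SE 0.60), Csf3 (8.03, SE 0.50), Prok2 (7.06, SE 0.57), the stromelysin gene Mmp3 (6.22, SE 0.69) and the connexin gene Gja1 (6.22, SE 0.50), the last pair well above background on 3 of 4 untreated arrays each. Among the lowest were Cysltr1, a leukotriene receptor gene (at least 9.55-fold lower), Ahrr (-3.94, SE 0.39) and Myof (-3.87, SE 0.23). Of 33 cytokines and chemokines 24 rose, 4 fell and 5 did not pass (24 and 4 adjusted over the list alone; median 2.07), and Il18 (-1.53) and Csf1 (-1.21) fell. The camera adjusted p was 2.2e-07, and adjusted p = 0.54 with an estimated correlation. Of 24 NF-kB targets and feedback regulators 19 rose and 5 did not pass (19 adjusted over the list alone; median 0.89), with Zc3h12a at 2.84 and Tnfaip3 at 2.43. Camera gave adjusted p = 8.3e-08, and adjusted p = 0.33 with an estimated correlation. Of 34 interferon-stimulated genes 20 fell and 14 did not pass (22 adjusted over the list alone; median -1.11), among them Ifit2 (-3.71, SE 0.58), Gbp2 (-2.35, SE 0.35) and Irf1 (-1.53, SE 0.18). By camera the list had adjusted p = 8.9e-08, against adjusted p = 0.77 with an estimated correlation. The fall was uneven between arrays. The list mean of replicates 1 to 4 was 4.76, 4.08, 4.50 and 4.35 untreated, and 2.18, 3.95, 2.48 and 3.65 with LPS. Replicates 1 and 3 thus carried most of it, and LPS replicate 2 lay close to the lowest untreated array.

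Lysosome and autophagy genes were lower in 19 of 32 cases and higher in 1 in arrays labelled fld, with 12 not past the test (21 and 1 adjusted over the list alone). This list reached adjusted p = 5.6e-05 by camera and adjusted p = 0.77 with an estimated correlation. LXR targets and cholesterol-handling genes fell in 9 of 17 cases and rose in 2, with 6 not past the test (11 and 2 adjusted over the list alone), with Abcg1 at -2.22 and Nceh1 at -2.13. The camera adjusted p was 0.010, and adjusted p = 0.77 with an estimated correlation. Fatty acid oxidation genes and PPAR targets fell in 14 of 28 cases and rose in 2, with 12 not past the test (16 and 2 adjusted over the list alone), with Cpt1a at -1.85 and Acaa2 at -0.98. Camera gave adjusted p = 0.0037, and adjusted p = 0.54 with an estimated correlation. Genes of the unfolded protein and integrated stress responses rose in 9 of 24 cases with 15 not past the test (9 adjusted over the list alone). By camera the list had adjusted p = 0.010, against adjusted p = 0.54 with an estimated correlation. AP-1, immediate early and MAPK phosphatase genes rose in 11 of 24 cases and fell in 4, with 9 not past the test (11 and 4 adjusted over the list alone). This list reached adjusted p = 0.029 by camera and adjusted p = 0.77 with an estimated correlation. That call was lost without fld LPS replicate 2 (camera adjusted p = 0.0532), fld LPS replicate 4 (0.0806) or both arrays labelled fld replicate 4 (0.0764), and with normexp and extreme local backgrounds reset (0.135), where the stress response call was lost too (0.162).

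Without a call for the list, 7 of 27 TLR4 pathway components rose and 6 fell in arrays labelled fld (7 and 6 adjusted over the list alone), 4 of 21 eicosanoid genes rose and 6 fell (4 and 6), 9 of 28 glycerolipid synthesis genes rose and 5 fell (10 and 7), and 4 of 18 lipid droplet, uptake and lipolysis genes rose and 6 fell (5 and 7; median 0.08, mean -0.07). Lipa fell by 2.74 and Hilpda rose by 2.69. Of 21 glycolysis and hypoxia genes 6 rose and 6 fell (6 and 6 adjusted over the list alone; median -0.07, mean 0.11), of 18 oxidative stress genes 5 rose and 4 fell (5 and 6), of 17 alternative activation genes 3 rose and 6 fell (3 and 7), of 30 sterol and fatty acid synthesis genes 3 rose and 3 fell (3 and 3), of 28 cell cycle genes 2 rose (2), and of 35 oxidative phosphorylation genes 2 rose and 4 fell (0 and 1). The oxidative phosphorylation list was called lower without fld LPS replicates 1 (camera adjusted p = 0.0374) or 3 (0.0165), and the cell cycle list without fld LPS replicate 3 (0.0032).

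Of the 6922 calls in arrays labelled fld, 5780 did not overlap, as did 6575 of all features, where chance gives 2.86%. With median scaling the split was 1965 higher and 4670 lower, 29.6% higher against 54.6% with the 75th percentile, and the median of all features moved to -0.18. With the planned normexp background the count was 1358, and Tnf, Ccl2, Il12b and Cysltr1 were among the calls that ended. With extreme local backgrounds reset 66.6% of the calls were higher. Without both arrays labelled fld replicate 4 the count was 5348, of which 5017 were among the 6922.

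**Figure D2:**
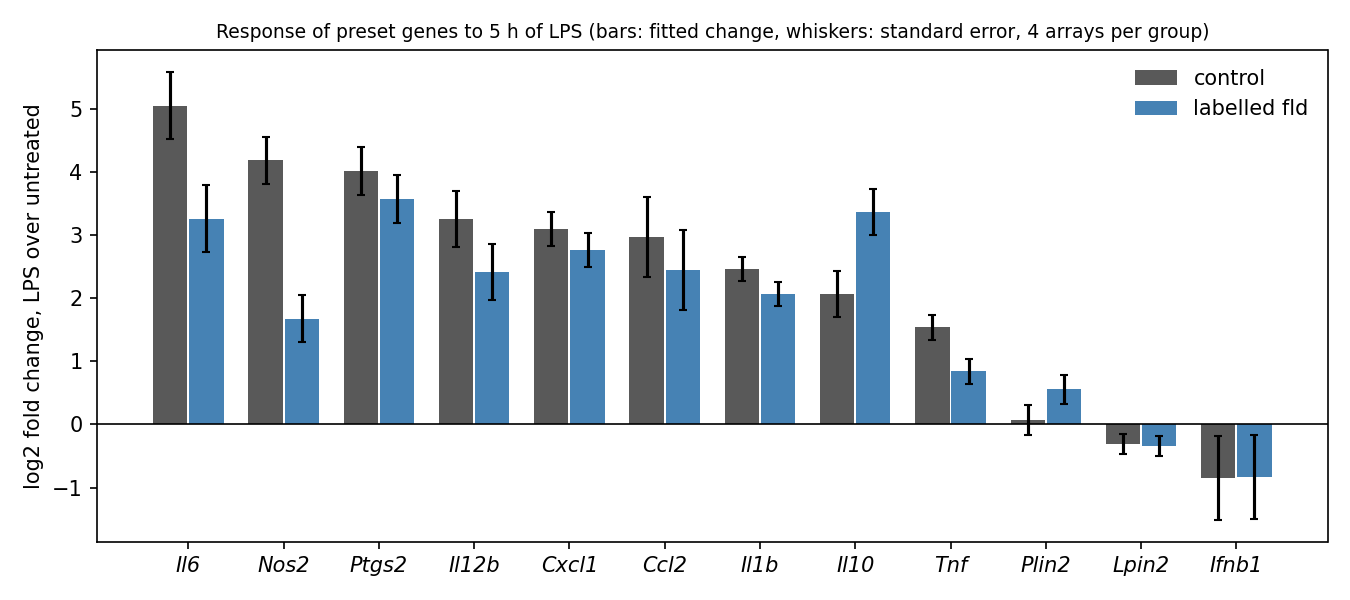
Log2 fold change of LPS over untreated (vertical axis, bars from 0, error bars 1 SE from limma, n = 4 arrays per group) for 12 genes fixed for naming, in control arrays (grey) and arrays labelled fld (blue). Il6, Ptgs2, Cxcl1, Il1b, Il10, Tnf and Ccl2 rose in both. Nos2 in untreated control arrays and Il12b in both untreated groups were not well above background, so these bars are fitted values and not folds.

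The LPS responses of the genotypes were close to each other across features, with a Pearson correlation of 0.853 and a Spearman correlation of 0.763 over 17462 features, which are not independent replicates. Both comparisons called 1876 features higher, where independent lists would share 549, and 2050 lower, where independent lists would share 469. The responses were computed from separate arrays, though their calls share the estimate of spread per gene. In all, 5 features were called in both with opposite signs. The difference between the responses was called by limma for 0 of 17462 features at an adjusted p under 0.05, with a smallest adjusted p of 0.0834. At an unadjusted p under 0.05 there were 1629, where 873 would come by chance. The response in arrays labelled fld minus that in control arrays was -2.51 for Nos2 (adjusted p = 0.16), -1.79 for Il6 (0.47), -0.69 for Tnf (0.44), 1.29 for Il10 (0.44), -0.39 for Il1b (0.70) and 0.00 for Ifnb1, none past the test. The Nos2 value is fitted from untreated control arrays that were not well above background, so its size is not measured. Without control untreated replicate 3 the Il6 difference was -1.02 (adjusted p = 0.32).

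As lists, 7 groups of genes responded lower in arrays labelled fld, each with 0 members called by limma over all features. With an estimated correlation none was called, with adjusted p from 0.71 for the cytokine list to 0.83 for the oxidative phosphorylation list. The lists were interferon-stimulated genes (median -0.63, camera adjusted p = 1.3e-06), NF-kB targets (-0.32, 1.7e-05), cytokines and chemokines (-0.52, 0.00030), sterol and fatty acid synthesis genes (-0.28, 0.00086), TLR4 pathway components (-0.08, 0.0055), unfolded protein and integrated stress response genes (-0.25, 0.0063) and oxidative phosphorylation genes (-0.09, 0.022). The last 3 calls ended with cyclic loess, at camera adjusted p of 0.173 (median -0.0014), 0.414 (-0.16) and 0.896 (-0.0097), and with quantile scaling, at 0.123 (median 0.0046), 0.422 (-0.13) and 0.886 (0.017). The interferon median was -0.29 without fld LPS replicate 1 and -0.39 without fld LPS replicate 3, and the cytokine median -0.29 without control untreated replicate 3, on which mast cell markers lay at -0.62 against 1.31 to 1.55 on the rest of its group. When adjusted over the list alone, 2 NF-kB targets, 2 TLR4 components and 1 cytokine passed, and no member of the other 4 lists. The interferon, cytokine and NF-kB lists were already higher in untreated arrays labelled fld (medians 0.72, 0.52 and 0.33). They were not among the lists called with LPS. The difference between responses subtracts the untreated difference, so these lower responses do not show a lower level under LPS. Over all features the difference between responses ran with signal, with a median of 0.22 in the dimmest and -0.08 in the brightest of 3 equal classes. Against 10000 random lists of matched signal, the medians of 5 lists lay below the central 95% and those of the TLR4 and oxidative phosphorylation lists lay inside it. The TLR4 call was lost without fld LPS replicate 4 (camera adjusted p = 0.152), the sterol call without control LPS replicate 3 (0.0635), the stress response call without fld LPS replicate 3 (0.0617), and the oxidative phosphorylation call without any of 6 arrays (control untreated replicate 4, 0.275; control LPS replicate 3, 0.232; fld untreated replicates 3 and 4, 0.0549 and 0.0789; fld LPS replicates 2 and 4, 0.108 and 0.218). Calls were gained for large peritoneal macrophage markers without fld untreated replicate 1 (0.0435), fld LPS replicate 1 (0.0126) or fld LPS replicate 3 (0.0377), for lysosome genes without fld LPS replicate 1 (0.0385), for cell cycle genes without fld LPS replicate 3 (0.0018) and for AP-1 genes without fld LPS replicate 4 (0.0367). The count of 0 became 1 without control untreated replicate 4, control LPS replicate 3 or fld LPS replicate 1, and other tools and settings gave 0 to 18. With median scaling the median difference between responses over all features was -0.22.

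Without LPS, arrays labelled fld gave higher signal than control arrays for many dim transcripts and, at the preset correlation of camera, for inflammatory genes as lists, and lower signal for a few genes, Nr1d1 among them. With an estimated correlation no list call held, each at adjusted p = 0.98. Nos2 was higher by at least 1.49-fold (adjusted p = 0.0080), the cytoskeletal gene Shroom3 by 2.86 log2 units (SE 0.53, adjusted p = 0.0087) and the potassium channel gene Kcnj11 by at least 1.23-fold (adjusted p = 0.0068). Shroom3 was well above background on 1 of 4 control arrays. Nr1d1, a transcriptional repressor of the circadian clock, was lower (-2.63, SE 0.46, adjusted p = 0.0056), as were the organic anion transporter gene Slco2b1 (-2.72, adjusted p = 0.014), the clock-controlled factor Tef (-1.10, adjusted p = 0.0028), the lectin gene Cd209a (-1.58, adjusted p = 0.0065) and the cell cycle inhibitor gene Cdkn2a (-1.39, adjusted p = 0.0093). In total 898 of 17462 features passed limma's test, 860 higher and 38 lower in arrays labelled fld. Il6 (1.84, adjusted p = 0.060), Il1b (0.65, adjusted p = 0.068), Tnf (0.52, adjusted p = 0.16) and Ifnb1 (1.21, adjusted p = 0.36) did not pass, nor did the brightest Lpin1 probe. Il6 was called without control untreated replicate 3, which lay below the rest of its group (1.08, adjusted p = 0.032), without control untreated replicate 1 (2.18, 0.035) or without fld LPS replicate 4 (1.84, 0.045). Tnf was called without control untreated replicate 1 (0.69, 0.048), and Il1b without fld LPS replicate 4 (0.65, 0.043) or both arrays labelled fld replicate 4 (0.74, 0.041). Array weights called all 3, Il6 at 1.58 (0.025), Tnf at 0.70 (0.028) and Il1b at 0.55 (0.043).

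Interferon-stimulated genes in untreated arrays labelled fld were higher as a list (median 0.72), though over all features only Gbp2, a guanylate-binding protein gene, rose (1.28, just within the threshold) and 33 of 34 did not pass (5 rose adjusted over the list alone). The camera adjusted p was 9.0e-06, and adjusted p = 0.98 with an estimated correlation. NF-kB targets were higher (median 0.33), with 4 of 24 called and 20 not (7 adjusted over the list alone): Malt1 (0.66), Socs1 (0.94), Traf1 (0.82) and Nfkb1 (0.39). Camera gave adjusted p = 0.0013, and adjusted p = 0.98 with an estimated correlation. Of 33 cytokines and chemokines Cxcl9 (1.76) and Tnfsf15 (0.93) rose and 31 did not pass (5 adjusted over the list alone; median 0.52). By camera the list had adjusted p = 0.0045, against adjusted p = 0.98 with an estimated correlation. B cell markers were lower as a list (median -0.14), with 1 of 16 lower and 15 not past the test (1 adjusted over the list alone). This list reached adjusted p = 0.0045 by camera and adjusted p = 0.98 with an estimated correlation. Glycolysis and hypoxia genes were lower as a list with 0 of 21 called by limma (0 adjusted over the list alone; median -0.13). The camera adjusted p was 0.026, and adjusted p = 0.98 with an estimated correlation.

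These list calls in untreated cells rested on single arrays in part. The cytokine call was lost without control untreated replicate 3 (camera adjusted p = 0.159) or fld untreated replicate 3 (0.236), and the B cell call without control untreated replicate 1 (0.0648), control untreated replicate 3 (0.159) or fld untreated replicate 2 (0.0733). Without control untreated replicate 3, on which mast cell markers lay at -0.62 (1.31 to 1.55 on the rest of its group), the medians were 0.28 for cytokines, -0.06 for B cell markers and -0.02 for glycolysis genes. The glycolysis call was lost without control untreated replicate 3 (0.0643), control untreated replicate 4 (0.0663), fld untreated replicate 2 (0.0581), fld untreated replicate 4 (0.0689) or both arrays labelled fld replicate 4 (0.0597), and with median scaling (0.0595) or cyclic loess (0.0808). The gene calls were as narrow: Cxcl9 was lost with any of 5 arrays left out (adjusted p up to 0.0968), Tnfsf15 with any of 6 (0.0911), Malt1 with any of 7 (0.110), Socs1 with any of 6 (0.114), and Gbp2 and Nfkb1 with any of 10 (0.168 and 0.125). The lysosome and autophagy list was called lower without control untreated replicate 4 (0.0051) or fld untreated replicate 2 (0.0280). The other lists held few called members: Irak2 (0.67) among TLR4 components, Cidec (1.005) and Plin5 (0.78) among lipid droplet genes, Ppard (0.47) among PPAR genes and Atg7 (-0.47) among autophagy genes. No member of the AP-1, eicosanoid, glycerolipid synthesis, sterol synthesis, LXR, cell cycle, stress response, oxidative stress, alternative activation or oxidative phosphorylation lists was called by limma in untreated cells, over all features or adjusted over the list alone.

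Of the 898 calls 869 did not overlap, as did 2745 of all features, where chance gives 2.86%. The count was 423 and 461 without control untreated replicates 2 and 3, 357 and 495 without fld untreated replicates 1 and 4, and 1618 without fld LPS replicate 4, which enters through the shared estimate of spread. The share of higher calls was 95.8%. It was 85.2% with median scaling (653 higher, 113 lower; median of all features -0.12), and 71.6% with cyclic loess (444 higher, 176 lower). With normexp and extreme local backgrounds reset, 38 features were called, 33 higher and 5 lower, 37 of them among the 898. The median size of the 898 differences went from 0.96 (SE 0.21) to 0.40 (SE 0.17), and 99.8% kept their sign: most calls ended because the differences shrank by more than their errors. Nr1d1 and Tef kept the call. Nos2 (0.35), Shroom3 (0.71), Kcnj11 (0.28), Slco2b1 (-1.36), Cd209a (-0.61), Cdkn2a (-0.30), Cxcl9 (0.68) and Tnfsf15 (0.33) lost it with smaller differences. Gbp2 (1.22), Malt1 (0.65), Socs1 (0.92) and Nfkb1 (0.36) lost it with differences close to those before, at adjusted p of 0.134 to 0.155. With normexp as planned limma called 0 features, with 272 at an unadjusted p under 0.05. Without both arrays labelled fld replicate 4 the count was 1116, 1057 higher, and 798 of these were among the 898.

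With LPS, arrays labelled fld again gave more features with higher signal, a direction that turned with median scaling (2000 higher, 6455 lower), and none of the inflammatory genes fixed for naming passed the test. Il6 (0.06, adjusted p = 0.96), Tnf (-0.17, adjusted p = 0.65), Nos2 (-0.51, adjusted p = 0.43) and Il10 (0.89, adjusted p = 0.12) did not pass, nor did Il1b (0.25), Ptgs2 (0.22), Plin2 (0.35) or the brightest Lpin1 probe. Tnf was called lower with median scaling (-0.57, adjusted p = 0.028), and Il10 higher without fld LPS replicate 3 (1.19, adjusted p = 0.029). Of genes for fatty acid oxidation and lipid droplets, these were higher: the coactivator gene Ppargc1a by 1.77 log2 units (adjusted p = 0.0017), Cpt1b by 1.40 (adjusted p = 0.0037), Ppard by 0.998 (adjusted p = 7.8e-05) and the lipid droplet gene Plin5 by 1.0999 (adjusted p = 0.00081). With 2810 of 17462 features higher, such calls do not set these lists apart, and camera called neither list. In total 2970 of 17462 features passed limma's test, 2810 higher and 160 lower in arrays labelled fld.

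Among features whose arrays do not overlap, the highest with LPS by fitted value were Olfr1222 (2.73, adjusted p = 0.0023), Lypd6 (at least 3.89-fold), Sorbs2 (2.54, adjusted p = 0.0023), Asic2 (at least 2.48-fold), Dmrtb1 (2.51, adjusted p = 0.00067) and Slc17a4 (at least 2.47-fold). For genes given as a bound the rank rests on signal below background and is not measured. Among the lowest were Tanc1 (-1.21, adjusted p = 0.0098) and Tjp1, of tight junctions (-1.25). Of 33 cytokines and chemokines Tnfsf15 was higher (1.51, adjusted p = 0.00035), Csf1 (-0.69) and Il23a (-0.88) were lower and 30 did not pass (1 rose adjusted over the list alone). Csf1 was lost with any of 5 arrays left out (adjusted p up to 0.103) and Il23a with any of 7 (0.105). Of 18 lipid droplet, uptake and lipolysis genes 4 were higher and 14 did not pass (4 adjusted over the list alone): Plin5, Plin4 (0.58), G0s2 (0.82) and Mgll (1.11). G0s2 was lost with any of 3 arrays left out (adjusted p up to 0.0698) and Mgll with any of 11 (0.131). Of 28 fatty acid oxidation genes and PPAR targets 3 were higher and 25 did not pass (3 adjusted over the list alone), those named above. Over all features 2810 of 17462 were higher, and 2144 of 5821 in the dimmest of 3 equal classes of signal. Fosb (0.88, adjusted p = 0.0018) was the called member of the AP-1 list, Zfp36 (0.40) of the NF-kB list and Ptdss2 (0.46) of the glycerolipid synthesis list. None of 34 interferon-stimulated genes passed limma's test with LPS, over all features or adjusted over the list alone (median 0.17), though the list was called lower without fld LPS replicate 2 (camera adjusted p = 0.0324).

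By camera 5 lists were lower with LPS in arrays labelled fld, each at an adjusted p of 0.031, and each with adjusted p = 0.85 with an estimated correlation. All 5 calls ended with cyclic loess (camera adjusted p = 0.671 to 0.715), quantile scaling (0.301 to 0.574) and the filter on all 16 arrays (0.109 to 0.187), and all but the TLR4 call ended with median scaling (0.0855 to 0.347). The difference between genotypes ran with signal, with a median over all features of 0.52 in the dimmest and -0.05 in the brightest of 3 equal classes. Against random lists of matched signal 3 medians lay below the central 95%, and those of the TLR4 (-0.07) and lysosome (-0.07) lists lay inside it. Without fld LPS replicate 4 the TLR4 and lysosome medians turned positive (0.015 and 0.017) and that of the macrophage markers was -0.08. The sterol median was -0.03 without control LPS replicate 3 and -0.07 without fld LPS replicate 1, and the B cell median -0.02 without fld LPS replicate 1. Of 27 TLR4 components Ticam2, an adaptor gene, was lower, at least 1.04-fold, and 26 did not pass (0 adjusted over the list alone); of 32 lysosome and autophagy genes and of 18 large peritoneal macrophage markers (median -0.44) limma called 0, with 0 adjusted over the list alone. Of 30 sterol and fatty acid synthesis genes 2 were higher, Fads2 (0.89, adjusted p = 0.00054) among them, against the direction of the list (median -0.17), and 28 did not pass (2 adjusted over the list alone). Of 16 B cell markers Cr2 (-1.31) and Fcmr (-0.70) fell, the latter lost with any of 3 arrays left out (adjusted p up to 0.0652), and 14 did not pass (2 adjusted over the list alone). Cr2 results turned sign with the filter on all 16 arrays, where another probe stood for the gene, and with planned normexp. The direction of Cr2 is therefore not settled. The TLR4 call was lost without control LPS replicate 1 (camera adjusted p = 0.0797), control LPS replicate 2 (0.0894) or fld LPS replicate 4 (0.213), and the sterol call without control LPS replicate 2 (0.0551), control LPS replicate 3 (0.226) or fld LPS replicate 1 (0.211). The lysosome call was lost without control LPS replicates 1 (0.140) or 2 (0.0881) or fld LPS replicates 2 (0.0629) or 4 (0.359), the macrophage marker call without control LPS replicate 1 (0.0584) or fld LPS replicate 4 (0.1996), and the B cell call without control LPS replicates 2 (0.0644) or 3 (0.0510) or fld LPS replicate 1 (0.212). No member of the eicosanoid, LXR, cell cycle, stress response, glycolysis, oxidative stress, alternative activation or oxidative phosphorylation lists was called by limma in this comparison, over all features or adjusted over the list alone, and the oxidative phosphorylation list was called lower without fld LPS replicate 3 (0.0415).

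Of the 2970 calls 2701 did not overlap, as did 3545 of all features, where chance gives 2.86%. The share of higher calls was 94.6%. With median scaling 8455 features were called and 23.7% were higher (2000 higher, 6455 lower; median of all features -0.37), with quantile scaling 74.3% (1845 higher, 637 lower) and with cyclic loess 59.4% (1376 higher, 940 lower). With normexp and extreme local backgrounds reset 2111 were called (2041 higher, 70 lower), and the median size of the 2970 differences went from 1.03 (SE 0.22) to 0.61 (SE 0.17). There Asic2 (0.61), Cr2 (-0.20), Tjp1 (-0.27), Il23a (-0.37) and G0s2 (0.43) lost the call because their differences shrank, and Ticam2 lost it with a changed sign (0.18). With normexp as planned limma called 0, with 500 at an unadjusted p under 0.05. Without both arrays labelled fld replicate 4 the count was 2315, of which 2235 were among the 2970. The genotype differences without and with LPS, from separate arrays, had a Pearson correlation of 0.638 and a Spearman correlation of 0.541 over features, which are not independent. Both called 728 features higher (138 for independent lists) and 12 lower (0.348 for independent lists). The comparisons may share mice, since the design text names 4 control and 4 fld mice, and they share the estimate of spread per gene. The overlap of independent lists is therefore no measure of chance here.

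**Figure D3:**
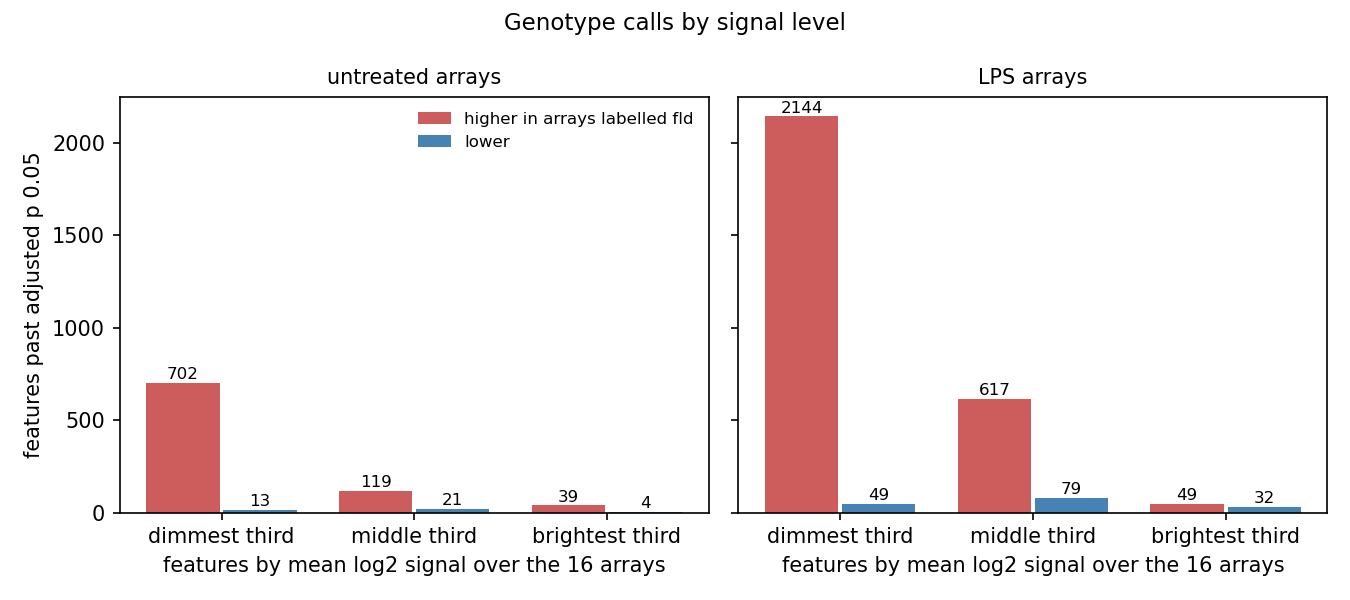
Number of features called higher (left bars) and lower (right bars) in arrays labelled fld than in control arrays, by 3 equal classes of mean signal, untreated and with LPS (adjusted p under 0.05, limma, n = 4 arrays per group). From the dimmest to the brightest class 702, 119 and 39 features were higher untreated and 13, 21 and 4 lower. With LPS 2144, 617 and 49 were higher and 49, 79 and 32 lower.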

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

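The tests of slide and scan, of loss of the Lpin1 transcript, of an exchange with a control array and of control RNA mixed in were chosen only after the result was seen, and so were the splits with the genotype effect removed and the fit without the arrays labelled fld replicate 4.

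Most calls between genotypes were higher in arrays labelled fld, 860 of 898 untreated and 2810 of 2970 with LPS, though with median scaling most calls with LPS were lower (2000 higher, 6455 lower). A dependence on signal level as the whole cause predicts a low share of higher calls among the brightest of 3 equal classes. With LPS that share was 60.5%, as such a dependence predicts. Untreated it was 90.7%, against the prediction, but this is 39 of only 43 calls. The dimmest class held 715 of the 898 untreated calls, and its median over all features was 0.27 against 0.04 in the brightest. So few bright calls cannot set a dependence on signal level aside. A single array, fld LPS replicate 4, is argued against, since 2342 features were called without it. A narrowed signal range on the arrays may account for part: dim spike-ins sat closer to bright ones on arrays labelled fld by 0.11 (SE 0.04) untreated and 0.19 (SE 0.06) with LPS, each at an exact permutation p of 0.0286, the smallest possible, against 0.18 and 0.44 for gene features. On the same scale every spike-in was itself higher on arrays labelled fld. For example, (+)E1A_r60_a107 read -1.28 in control and -0.86 in labelled fld arrays untreated, and -1.13 and -0.14 with LPS. The brightest, (+)E1A_r60_1, read 9.64 and 9.73 untreated, and 9.86 and 10.36 with LPS. Such a rise is thus not particular to genes of the cells, whose calls had a median size of 0.96 untreated and 1.03 with LPS. The slide and scan of a group cannot be told apart from genotype, since 0 slides held more than 1 group, and genotype stays open with loss of the Lpin1 transcript: replicate 4, which carries Lpin1 signal, showed 105% (untreated) and 168% (LPS) of the shift of the other arrays labelled fld, but that is 1 array per comparison, and the LPS one has the narrowest signal range of its group.

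Interferon-stimulated genes were higher as a list in untreated arrays labelled fld, by a median of 0.72. The list was called by camera at its preset correlation, but had adjusted p = 0.98 with an estimated correlation. No single array accounts for it, since the lowest median with 1 untreated array left out was 0.60. A dependence on signal level is argued against, since the 95th percentile of 10000 random lists of matched signal was 0.098. An activated state of untreated cells labelled fld is a hypothesis that was not tested. Slide and scan are open here too, and the exact permutation test on the list mean per array gave p = 0.0857 (n = 4 per group).

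The arrays labelled fld replicate 4 carried Lpin1 signal on 3 neighbouring probes, -1.62 untreated against -6.72 to -6.07 in the other arrays of its group, and this probe mean, which does not enter the tests between groups, lay 1.496 above the control mean. An exchange with a control array is argued against, since 0 control arrays lacked the signal, as is control RNA mixed into the sample untreated, where it cannot exceed the control level. With LPS the Lpin1 difference from control was 0.19, but a mixture of such RNA lies between its sources, and 94.2% of the features that departed from the other arrays labelled fld (65 of 69) lay outside the range of the control arrays on the far side. These features were selected for departing, and many move together across arrays. They cannot exclude a mixture with LPS, where the Lpin1 level (-3.03) lay within the range of the control arrays (-3.47 to -2.86). A mouse of another genotype under the fld label may be a source, and stays open: 1.45% of the features that departed in both arrays labelled fld replicate 4 (1 of 69, Rnf144a, with Lpin1 itself left out) lay within 20 Mb of Lpin1, against 0.75% of all features (Fisher's exact p = 0.41).

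Other splits of the same arrays bear on chance. For LPS against untreated 1 of 35 splits, the real one, gave as many calls in control arrays (5143, highest other 5) and in arrays labelled fld (6922, highest other 10). For fld against control it was again 1 of 35, untreated (898, highest other 19) and with LPS (2970, highest other 1). A share of 1 of 35 is the smallest this test can give, and it argues against chance for these 4 counts without excluding it. The other splits mix the groups and so carry the real difference into the spread, and their low counts do not measure chance. For the difference between responses 13 of 100 splits gave at least as many features at an unadjusted p under 0.05 (1629, highest other 4938), but moved labels carry the genotype effect into that difference, so this count decides nothing. With the genotype effect of each feature subtracted first, 7 of the same 100 splits did (highest other 2793), so chance cannot be excluded.

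The LPS response differed between genotypes in 7 lists by camera, lower in arrays labelled fld, with median differences of -0.52 for cytokines and chemokines, -0.63 for interferon-stimulated genes, -0.32 for NF-kB targets, -0.079 for TLR4 components, -0.28 for sterol and fatty acid synthesis, -0.25 for the stress responses and -0.092 for oxidative phosphorylation. With an estimated correlation none was called, at adjusted p = 0.71 to 0.83. The cytokine, interferon and NF-kB lists were already higher in untreated arrays labelled fld (medians 0.52, 0.72 and 0.33), which enters this difference with its sign turned. The TLR4, stress response and oxidative phosphorylation calls ended with cyclic loess and with quantile scaling. Against random lists of matched signal the TLR4 and oxidative phosphorylation medians lay inside the central 95%.

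Single arrays stood apart from the other 3 of their group in 16 of 339 groups of values tested (4.72%), where chance gives about 1 in 20. In fld untreated replicate 4 the share of spots well above background was 62.2% (others 64.9% to 65.2%). List means stood apart for cytokines in control LPS replicate 3 (2.60; others 2.72 to 2.74), eicosanoid genes in control LPS replicate 4 (1.35; 1.24 to 1.25), cell cycle genes in fld LPS replicate 3 (0.43; -1.33 to -1.09), glycolysis genes in control untreated replicate 1 (2.99; 3.09), mast cell markers in control untreated replicate 3 (-0.62; 1.31 to 1.55) and adipocyte markers in control untreated replicate 4 (-2.50; -2.81 to -2.77). Among genes, Il6 stood apart in control untreated replicate 3 (-0.60; 2.30 to 2.69) and in fld LPS replicate 4 (7.31; 6.60 to 6.69). Tpbpa did in control untreated replicate 3 (-5.76; -7.31 to -7.13), Gja1 in control untreated replicate 1 (-5.42; -3.90 to -3.68) and Sorbs2 in control untreated replicate 4 (-7.15; -6.12 to -5.94). Rnf144b did in fld LPS replicate 4 (-5.77; -4.19 to -3.91), Slco2b1 in control LPS replicate 4 (-0.29; -1.26 to -1.14) and Nav1 in control LPS replicate 1 (-1.40; -0.88 to -0.80). The value of Lpin1 in fld untreated replicate 4 is the one weighed above.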

How the results depend on the processing

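Cyclic loess, normexp with extreme local backgrounds reset and the fit without both arrays labelled fld replicate 4 were chosen only after the data were seen. The cause of each change was not tested unless given, and not every single list or gene that changed sides is named. In counts of calls (LPS in control, LPS in labelled fld, genotype untreated, genotype with LPS, difference between responses), the values that moved by over 1.5 times were these. Quantile scaling gave 542 for genotype untreated and 13 for the difference, and median scaling and the authors' value table, which are the same up to rounding, gave 8455 for genotype with LPS and 7 for the difference. Planned normexp gave 1107, 1358, 0 and 0 for the first 4. With it the Pearson correlation of the responses, which is no count and was not held to that limit, was 0.943 against 0.853. Under planned normexp 10 and 4 spots with local backgrounds over 10 times their array's median compressed the signal of control LPS replicate 2 and fld LPS replicate 1 to a log2 range of 0.21 and 0.41 from the 5th to the 75th percentile, against 2.02 to 3.41 on the other arrays. Normexp with all 21 such spots reset gave 38 for genotype untreated. Probes well above background on all 16 arrays gave 466 for genotype untreated, array weights 2217 and the arrays of the 2 groups alone 1689. The difference was called for 11 features with array weights, 18 with cyclic loess, 10 with the replicate block across genotypes and 7 with the random replicate block. At least 1 log2 unit gave 1527, 1912, 399 and 1556, and an adjusted p under 0.01 gave 3218, 4081, 228 and 1821, fewer by construction. With 1 array left out the counts were 4163 to 5884, 5324 to 7275, 357 to 1618, 2133 to 3258 and 0 to 1.

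Lists called were 8, 8, 5, 5 and 7. For genotype with LPS the number was 0 with quantile scaling, cyclic loess and the filter on all 16 arrays, 2 with median scaling, the value table and without both arrays labelled fld replicate 4, 9 with normexp, 13 with it reset and 17 without the filter. For the difference it was 4 with quantile scaling and cyclic loess and 11 without the filter. An estimated correlation gave 1, 0, 0, 0 and 0, and fry, which asks another question, 1, 0 and 0 for genotype untreated, genotype with LPS and the difference. With 1 array left out the lists were 3 to 6 for genotype untreated (3 without control untreated replicate 3) and 1 to 6 for genotype with LPS (1 without control LPS replicate 2).

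Signs turned for few reported results. With quantile scaling Atp5b in LPS control was -0.028 and the oxidative phosphorylation list of the difference had an adjusted p of 0.886. With normexp, Ticam2 was 0.29, 0.32 and 0.094 in LPS control, LPS labelled fld and genotype with LPS, Atp5b -0.16 and -0.16, Cycs -0.10, Uqcrc1 -0.26 and -0.14, Cr2 0.42 and 0.11, Krt18 0.22, Krt8 0.16, Col3a1 0.61 and Mcoln3 0.12 (genotype with LPS), and the stress response list in labelled fld had an adjusted p of 0.675. With it reset, Mcoln3 was 0.20 and Ticam2 0.18 in genotype with LPS. With the filter on all 16 arrays, where another probe stood for the gene, Cr2 was 0.19, 0.44 and 0.47. With fry the glycolysis list in labelled fld had an adjusted p of 0.0254. Of the reported gene results, 5057 of 5328 kept their status with 1 array left out, 261 lost a call and 10 gained one. With normexp reset 289 of 333 kept their status, 42 lost a call and 2 turned sign. Results not called in the main fit that stayed so count as kept, so these shares do not measure how many calls held.

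The replicate numbers pair the arrays by number only. Same-numbered untreated and LPS arrays deviated together with correlations of 0.16, 0.09, 0.25 and 0.09 in control and -0.08, -0.08, -0.10 and 0.20 in labelled fld arrays, not all over 0.1, and not every array correlated best with its own number. The replicate block within genotype gave 4955, 6978 and 0 calls for the LPS responses and their difference, and it cannot give the comparisons between genotypes. The slide as a block was not run, because each slide held 1 group. Signal over background limits dim features most: a surrogate stands for the dimmest spots, and 715 of the 898 and 2193 of the 2970 genotype calls lay in the dimmest of 3 equal classes.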

Other observations

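The clock test was planned before its result was seen, while the clock genes themselves were chosen after 2 of them led the lower calls.

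Some markers of other cells changed with LPS. Among 7 neutrophil markers S100a8 and Camp rose and Mmp8 fell in both genotypes: by 3.46, 3.07 and -2.88 in control cells and by 4.49, 2.50 and -1.65 in cells labelled fld (3 and 1 adjusted over the list alone in control cells, 2 and 1 in cells labelled fld). Of 18 large peritoneal macrophage markers 3 rose and 2 fell in control cells (3 and 2 adjusted over the list alone) and 2 rose and 7 fell in cells labelled fld (2 and 7), Timd4 among them (-2.34). Of 18 small peritoneal macrophage, monocyte and dendritic markers 1 rose and 1 fell in control cells (0 adjusted over the list alone) and 4 rose and 3 fell in cells labelled fld (4 and 3). B cell markers fell in 3 and 4 of 16 cases (0 and 2 adjusted over the list alone). T and NK cell markers rose in 1 and 3 of 18 cases and fell in 0 and 1 (0, and 3 and 1, adjusted over the list alone), and Gzmb, a cytotoxic granule gene that stimulated macrophages can also hold, rose by 3.65 in cells labelled fld. Of 12 mesothelial and fibroblast markers 2 rose and 3 fell in control cells (2 and 3 adjusted over the list alone; median -0.29, mean 0.25), with Pdpn at 3.73, and 3 rose in cells labelled fld (3; median -0.24, mean 0.44), with Pdpn at 3.69 and Col1a1 at 2.22. Mast cell markers rose in 1 of 10 cases and erythroid and platelet markers fell in 1 of 6 in each genotype (1 and 1 adjusted over the list alone). Adipocyte markers fell in 1 of 3 in each (2 rose and 1 fell adjusted over the list alone in control cells, 1 fell in cells labelled fld), and of 3 eosinophil markers limma called 0 both ways. Of 13 housekeeping genes 2 fell in control cells (1 adjusted over the list alone), and 2 rose and 2 fell in cells labelled fld (2 and 2), Gusb among them (-1.32). None of these lists was called by camera with LPS, while fry called the neutrophil list in control cells (adjusted p = 0.0010) and in cells labelled fld (4.7e-05). By camera, B cell markers were called lower in control cells without control untreated replicates 2 (0.0109) or 4 (0.0194), control LPS replicate 3 (0.0476) or fld untreated replicate 4 (0.0448). They were in cells labelled fld without fld untreated replicate 2 (0.0242) or fld LPS replicate 4 (0.0457). Mast cell markers were called higher in control cells without control untreated replicates 2 (0.0385) or 4 (0.0380), and large peritoneal macrophage markers lower in cells labelled fld without fld LPS replicate 1 (0.0212).

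Between genotypes with LPS, T and NK markers were higher in arrays labelled fld in 4 of 18 cases (4 adjusted over the list alone): Cd3e (1.41, adjusted p = 0.00014), Cd4 (0.96), Cd8a (0.98) and Klrb1c (1.15). Over all features 2810 of 17462 were higher with LPS, and camera did not call this list. Mpo (0.85, adjusted p = 0.0012), S100a8 (0.75) and S100a9 (2.30) were higher among 7 neutrophil markers (4 adjusted over the list alone), Col1a1 (2.45, adjusted p = 0.0034), Col1a2 (1.39) and Krt8 (0.97) among 12 mesothelial and fibroblast markers (4), and Cd226 (0.85), Cx3cr1 (1.14), Flt3 (0.98) and Zbtb46 (0.56) among 18 small macrophage, monocyte and dendritic markers (4). S100a8 was lost with any of 9 arrays left out (adjusted p up to 0.124), S100a9 with any of 2 (0.0661) and Krt8 with any of 11 (0.155). Of 13 housekeeping genes Polr2a was higher (0.53) and Tbp lower (-0.34). Without LPS, Cd3e (0.85), Cx3cr1 (1.20) and Zbtb46 (0.52) were higher and Cd209a lower (-1.58), and Cx3cr1 was lost with any of 2 arrays left out (0.0556) and Zbtb46 with any of 7 (0.128). Mast cell, eosinophil and erythroid and platelet markers had 0 of 10, 0 of 3 and 0 of 6 members called by limma in both genotype comparisons, and 0 adjusted over the list alone. Of 3 adipocyte markers Cidec was higher untreated and limma called 0 with LPS, and untreated it called 0 neutrophil, mesothelial, large macrophage and housekeeping genes (1 neutrophil gene adjusted over the list alone). Untreated, lists were called for mast cell markers without control untreated replicate 3 (0.0034), for mesothelial markers without control untreated replicate 2 (0.0417) and for large peritoneal macrophage markers without fld untreated replicate 2 (0.0371).

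Of 15 measured genes of the circadian clock and its outputs, 7 were called by limma in a genotype comparison and 8 in neither (Ciart, Bhlhe41, Cry2, Usp2, Arntl, Clock, Cry1 and Nfil3). Nr1d1 was lower in arrays labelled fld both untreated (-2.63) and with LPS (-2.10, adjusted p = 0.0046), as was Tef (-1.10 and -0.60) and Per1 (-0.52 and -0.44). Dbp was lower untreated (-0.85, adjusted p = 0.022) and Nr1d2 with LPS (-0.81, adjusted p = 0.041), while Per2 was higher in both (0.69 and 1.08) and Per3 with LPS (1.04, adjusted p = 0.036). A hypothesis is that the clock phase of the mice or cells differed between the genotypes, which may also reflect the time at which each group was collected. Tested on the other clock genes, without Nr1d1 and Tef, the difference between genes of opposite phase and output genes was 0.46 untreated (exact permutation p = 0.0571) and -0.14 with LPS (exact permutation p = 0.486), with 9 output and 4 opposite genes and n = 4 arrays per group. The test leaves the hypothesis open, since neither value passed and their signs differ.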
